A study of Mus musculus with 6 samples.

How the data were processed

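Small RNAs were measured on 6 one-colour microarrays of mouse heart, 3 from infarcted (MI) and 3 from sham-operated myocardium, each hybridised with 1 total RNA sample. Per the labels, the 3′ ends of the RNA were first freed of phosphates with T4 polynucleotide kinase, and the dye Cy3 was then joined to them with T4 RNA ligase as pCp-Cy3. RNA ending in a phosphate, as many products of tRNA cleavage do, can take up the dye after this step. The label is joined to the end of every RNA in the sample, so a probe reports the intensity of whatever labelled RNA hybridised to it, and probes of different sequence are not comparable in level.

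The deposited files hold spot intensity on a linear scale, extracted with Agilent Feature Extraction 11.0.1.1 per the submitters' processing notes and the file headers. Per the file headers, the software subtracted a spatially detrended background from each spot's intensity and raised the lowest values to a small positive number. Nothing was scaled between arrays. On sham 3 alone the processed intensity had also been detrended across the slide, per the file headers, with a root mean square of 0.0913, and differed from the background-subtracted value by up to 46.0%. The header of the array design names the mouse build mm9, but no coordinates were used.

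Each array held 15228 spots, of which 14692 were not controls. Probes carry identifiers only, with a class code inside: TRF for tRNA-derived small RNAs (1767 probes), MIRNA (9709 probes) and PST (2716 probes), a code that the files do not expand. The files do not pair these identifiers with names of tRNAs, fragments or miRNAs. The planned comparisons by type of fragment, by amino acid of the parent tRNA, by lists of miRNAs typical of cell types, between fragments and their tRNAs and between miRNAs and their precursors were therefore not run, and no marker of a cell type could be read. A further 50 probes target mRNAs, with 10 spots each. The RefSeq table at hand (assembly GRCm38.p6) gave gene names for 46 of them.

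Samples were grouped by the ligation or sham operation in their titles. The spots that the software had marked as outliers (16 to 33 per array) were left out, and spots of one probe were averaged on the log2 scale. No spot was flagged as saturated. Since 11733 to 12074 of the 14192 small RNA probes were well above background on each array, each array's log2 intensities were scaled by subtracting their 75th percentile over all non-control probes. A small RNA was tested if it was well above background on at least 3 of the 6 arrays. The tests were limma 3.58.1 (lmFit and eBayes, in R 4.3.3) with 1 term for the group and Benjamini-Hochberg adjustment at 0.05. Adjusted p-values are over all tested RNAs unless said to be adjusted over the list alone, meaning 1 class. Classes were compared with camera (preset correlation 0.01, then an estimated one) and fry. Numbers of detected RNAs were compared with an exact two-sided permutation test, which for 3 against 3 arrays cannot give a p below 0.1.

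The rule for the RNAs to be named was fixed before the data were examined: the 8 largest rises and 8 largest falls among called tRNA-derived RNAs whose groups did not overlap, 5 of each for miRNAs and 2 of each for the remaining class. Because the files give identifiers only, 2 identifiers are printed in each direction, and the others are summarised as ranges. For the mRNA probes, which were outside that rule, a separate fit over the 50 probes was used. The result of 1 mRNA probe is not reported here.

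The 3 MI arrays and sham 1 lay on slide 1, and sham 2 and sham 3 on slide 2, so slide was tried as a block and slide 1 was also tested alone. Both rest on the contrast of the MI arrays with sham 1. In the test of slide 1 the lone sham array is assumed to vary like the MI arrays. The other settings, listed at the same time as that rule, were a normexp background correction with an offset of 50, quantile normalization, scaling by the median, scaling over RNAs detected on all 6 arrays, other filters, array weights, another variance model, outlier spots kept, another threshold, replicate number as a block, and each array left out in turn. The normexp correction used median pixel intensity, since the files have no mean. Chosen after seeing the data were the unscaled intensities, scaling to the high-signal RNAs (mean signal of at least 200 over the 6 arrays), a filter at that level with and without that scaling, the undetrended intensity, slide 1 alone, 25 scales each set by the median of 1 class at 1 level of signal, and the comparison of miRNA and tRNA-derived probes of equal signal. That comparison took, within each array, the mean log2 signal of miRNA probes minus that of tRNA-derived probes in steps of 1 log2 unit of mean signal from 1024 to 16384, and averaged the steps. Only its change between groups is read. Levels of mean signal, that of 200 included, are means of log2 signal over the 6 arrays. Group signals printed in intensity units with an SD are arithmetic means.

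The fit was tested on simulated arrays with the spread of the real MI and sham comparison, with 200 of 11955 RNAs changed in each round. It recovered 39.3% of changes of 1 log2 unit, 96.1% of changes of 2 units and 99.5% of changes of 3 units. With 2 sham arrays in place of 3 it recovered 0%, 93.3% and 98.8%. The simulated noise was independent between RNAs and drawn alike for every array, without slides. These shares therefore need not hold for the real arrays, where leaving out sham 1 gave 0 calls. The number of arrays limits the precision of each value. The labels do not say in so many words that each array came from a separate mouse, so p-values measure the spread between these samples.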

Results

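Small RNAs were profiled in the hearts of male C57BL/6J mice 3 days after surgery. In the myocardial infarction (MI) group the left anterior descending coronary artery, which supplies the front wall of the left ventricle, was tied off, and tissue was taken from the infarcted area (n = 3 arrays). In the sham group a thread was passed through the same region without tying it, and the corresponding tissue was taken (n = 3 arrays). The title of the study asks about tRNA-derived small RNAs (tsRNAs), fragments cut from mature or precursor tRNAs, and the same arrays carried probes for miRNAs. The 3 MI arrays shared a slide with sham 1, and sham 2 and sham 3 lay on another.

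Nearly every tsRNA and miRNA probe gave a signal well above background in both groups. The number of tsRNA probes detected was 1759 ± 4.36 in MI and 1747 ± 7.94 in sham (SD, n = 3 each) out of 1767, with an exact permutation p of 0.2. For miRNA probes it was 9630 ± 30.1 against 9556 ± 102 of 9709, with an exact p of 0.3. In the PST class, whose code the files do not expand, it was 605.3 ± 73.2 against 544.3 ± 60.0 of 2716, also with an exact p of 0.3. All 3 tests had an adjusted p of 0.3, and 3 arrays against 3 cannot give an exact p under 0.1. A mean signal of at least 200 intensity units, averaged on the log2 scale, was reached by 818 tsRNA probes (46.3%), 628 miRNA probes (6.47%) and 35 PST probes (1.29%). These probes are called high-signal. Their numbers do not compare amounts of RNA between classes.

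The 75th percentile of all probes, which set the scale of each array, was 68.6, 78.7 and 97.4 in the MI arrays and 49.6, 42.9 and 83.0 in the sham arrays. The choice of scale therefore moved every difference by the same amount on the log2 scale: the median over all tested RNAs was -0.07 with this scaling, 0.46 without scaling and 0.32 when each array was scaled to its high-signal RNAs.

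A set of tsRNAs gave several times more signal on the MI arrays than on the sham arrays, in calls that ended when slide was a block. Of 1758 tsRNA identifiers tested, limma called 26 higher in MI (adjusted p under the threshold of 0.05), by 0.95 to 2.77 on the log2 scale with a median of 1.48. It called 98 lower, by a median of -1.14. How many separate tsRNAs these identifiers stand for is not known. Adjusted over the list alone, 39 were higher and 228 lower. The largest rise was that of ASMM10SMR20TRF100004218TV1, with a signal of 590 ± 91.4 in MI and 59.6 ± 6.23 in sham (SD, n = 3 each), a log2 difference of 2.77 (SE 0.27, limma adjusted p = 0.0116). ASMM10SMR20TRF100005310TV1 rose from 1009 ± 86.4 in sham to 7947 ± 752 in MI, a log2 difference of 2.45 (SE 0.28, adjusted p = 0.0116). The 8 largest rises ran from 1.91 to 2.77 on the log2 scale, or 5.49 to 9.89 times in unscaled mean signal. In all 26, each MI value lay above each sham value, but the groups were apart in every called small RNA. The 26 were also apart in unscaled signals, where they differed by 1.48 to 3.30. Unscaled signals and scaling to the high-signal RNAs raised every difference (median over all tested RNAs 0.46 and 0.32, against -0.07). These 2 settings therefore favoured rises in advance. All 26 remained called with quantile normalization and with scaling to the high-signal RNAs, 20 of them without scaling and 16 with scaling by the median.

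**Figure D1:**
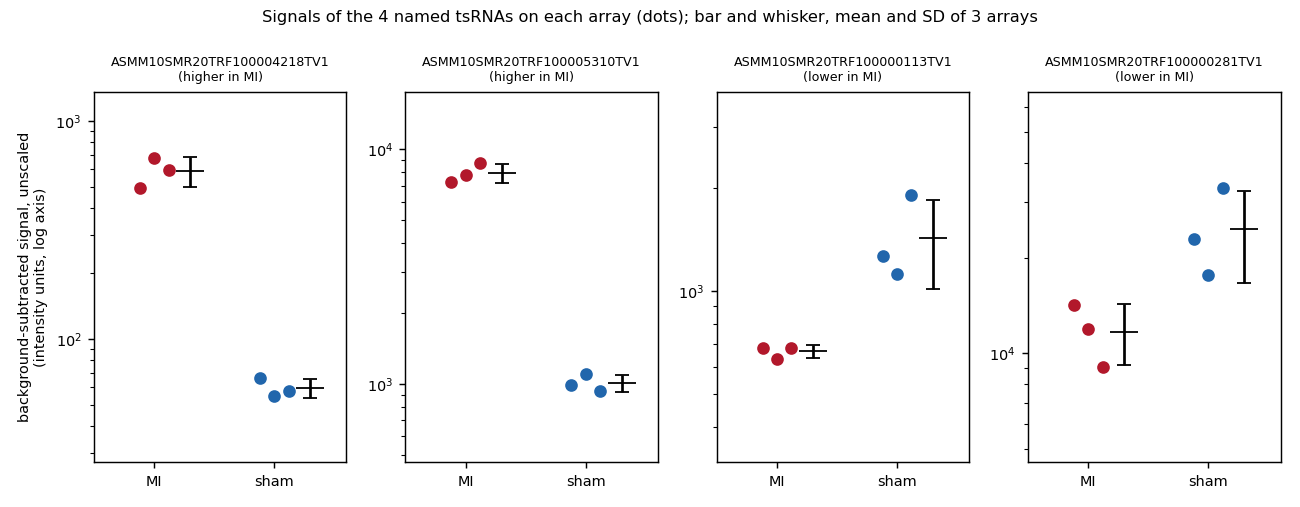
Unscaled background-subtracted signal (intensity units, log axis) of the 4 named tsRNAs on each MI and sham array, with the mean and SD of 3 arrays beside the dots. ASMM10SMR20TRF100004218TV1 and ASMM10SMR20TRF100005310TV1 were higher on every MI array (means 590 against 59.6 and 7947 against 1009), and ASMM10SMR20TRF100000113TV1 and ASMM10SMR20TRF100000281TV1 lower (666 against 1426 and 11730 against 24693), although the falls were called only with some scalings.

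The tsRNAs that were lower changed less, and their calls depended on the scale. The largest difference was that of ASMM10SMR20TRF100000113TV1, at 666 ± 27.8 in MI and 1426 ± 414 in sham (SD, n = 3 each), a log2 difference of -1.59 (SE 0.17, limma adjusted p = 0.0116), or -1.06 without scaling (adjusted p = 0.278). ASMM10SMR20TRF100000281TV1 was at 11730 ± 2553 against 24693 ± 8020, a log2 difference of -1.57 (SE 0.27, adjusted p = 0.0181), or -1.05 without scaling (adjusted p = 0.344). The 8 largest falls ran from -1.59 to -1.41 on the log2 scale. All 98 kept a negative sign with quantile normalization, without scaling and with scaling to the high-signal RNAs, but 10 stayed called in the first of these and 0 in the others (limma gave 290 and 276 tsRNAs an unadjusted p under 0.05). When each array was scaled to 1 class at 1 level of signal, the sign of some turned on 4 of 25 such scales. On that of miRNAs between 4096 and 8192 units 8 of the 98 remained negative, with a median of 0.26. Of the 51 miRNAs that set this scale, 40 were themselves called lower. It drew falls toward 0 by construction and cannot test them. With scaling to the high-signal RNAs 58 tsRNAs were called higher and 0 lower, and among high-signal RNAs alone, scaled to themselves, 70 tsRNAs were higher and 60 lower.

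The number of tsRNAs called changed with the slide and with single arrays. With slide as a block limma called 0 tsRNAs (385 with an unadjusted p under 0.05), and within slide 1, where the 3 MI arrays meet sham 1 alone, also 0 (723 unadjusted). There ASMM10SMR20TRF100004218TV1 still differed by 2.43 and ASMM10SMR20TRF100005310TV1 by 2.29 on the log2 scale (adjusted p = 0.264 with the block and 0.161 within the slide for both). The number was 0 without MI 2 (591 unadjusted), 0 without sham 1 (381 unadjusted), 41 without MI 3 and 548 without sham 3. Without sham 2 it was 111, of which 68 were higher and 43 lower, so that array alone turned the balance of rises and falls. The 98 lower tsRNAs had a median of -1.26 with the block (median SE 0.28) against -1.14 (0.19) without it.

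Falls outnumbered rises among miRNA calls as well. Of 9635 miRNA identifiers tested, 319 were called, 314 lower and 5 higher in MI, with a median of -1.22 among the lower ones. How many separate miRNAs they stand for is not known. Adjusted over the list alone, 271 were lower and 1 higher. The 5 largest falls ran from -1.94 to -1.85 on the log2 scale (limma adjusted p 0.0129 to 0.0181), which is 2.46 to 2.63 times more unscaled signal in sham than in MI. The 5 miRNAs called higher ranged from 0.68 to 1.63 (adjusted p 0.0369 to 0.0491), and of them 4 remained called with scaling to the high-signal RNAs, 2 without scaling, 1 with quantile normalization and 0 with scaling by the median. All 314 lower miRNAs kept a negative sign in these scalings, but their calls depended on the scale: 62 stayed called with quantile normalization, 26 with scaling to the high-signal RNAs and 0 without scaling (911 miRNAs with an unadjusted p under 0.05). Over all miRNAs, scaling to the high-signal RNAs gave 21 higher and 26 lower, and no scaling 6 higher and 0 lower. On 5 of the 25 scales set by 1 class at 1 level of signal some of the 314 turned, and on that of miRNAs between 4096 and 8192 units 88 remained negative. That scale was set by 51 miRNAs, of which 40 were among the 314 falls, so it cannot test them. Among the 628 high-signal miRNAs, scaled to the high-signal RNAs, 171 were lower and 29 higher. The slide block and slide 1 alone left 0 miRNA calls in limma (972 and 1714 with an unadjusted p under 0.05). Both rest on the same contrast, of MI with sham 1, in which the 314 falls had a median of -1.25 against -1.22, while the median SE was 0.29 with the block and 0.27 within the slide against 0.19. Leaving out single arrays gave 0 without MI 2 (1336 unadjusted), 0 without sham 1 (919 unadjusted), 56 without MI 3, 93 without sham 2 and 780 without sham 3.

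The median difference of miRNAs was largest between 4096 and 8192 intensity units, although 128 of the 314 called falls had a mean signal below 256 intensity units. These were 1.41% of the 9108 miRNAs tested below that level, against 35.3% of the 527 above it. In the range of 4096 to 8192 intensity units the median difference was -1.44 for 51 miRNA probes and -0.76 for 42 tsRNA probes, and without scaling it was -0.92 and -0.24. Above 16384 units the classes were closer, at -0.86 for 18 miRNA probes and -0.70 for 360 tsRNA probes, and from 256 to 1024 units the order turned, at -0.25 and -0.31. Over all probes with a mean signal of at least 200 the medians were -0.57 for miRNAs and -0.62 for tsRNAs. Below 256 units the medians of both classes lay between -0.15 and 0.13. A difference taken within each array is free of the scaling factor. Between 1024 and 16384 units, 196 miRNA probes stood at -0.32 ± 0.29 relative to 237 tsRNA probes of equal mean signal in MI and at 0.34 ± 0.18 in sham (log2, SD, n = 3 each). The change of -0.67, or 1.59-fold, had an exact permutation p of 0.1, the smallest that 3 against 3 arrays allow. The MI arrays stood at 0.01, -0.45 and -0.53 and the sham arrays at 0.37, 0.15 and 0.50. Within slide 1 the change was -0.69.

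**Figure D2:**
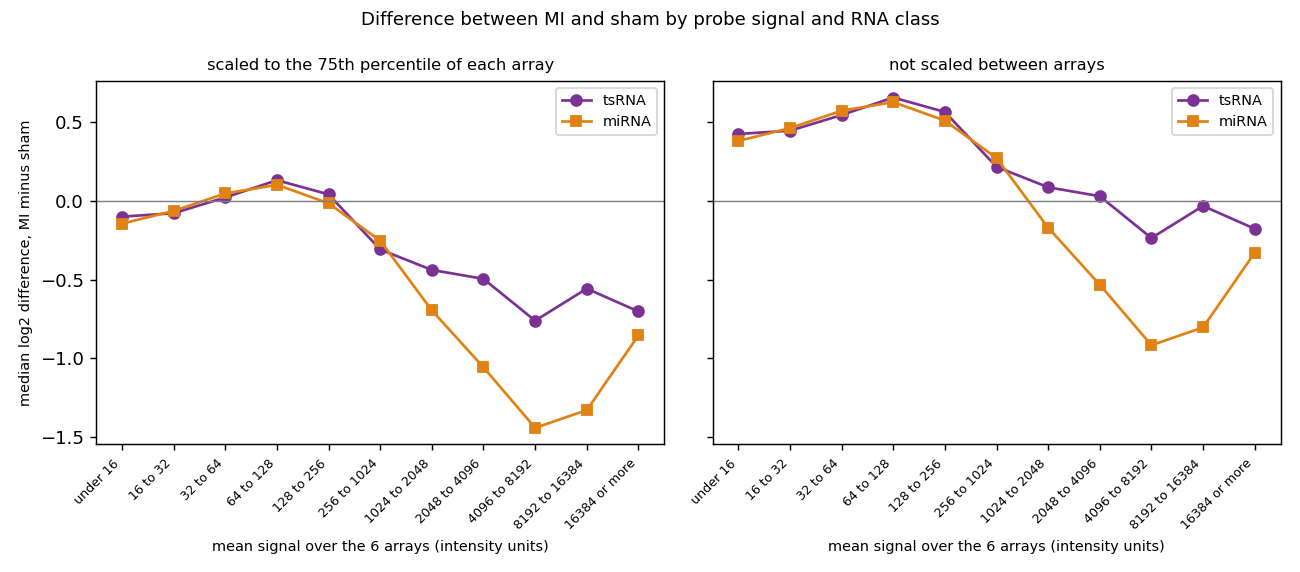
Median log2 difference, MI minus sham, of tsRNA and miRNA probes (vertical axis) at each level of mean signal over the 6 arrays (horizontal axis, intensity units), scaled to the 75th percentile of each array on the left and unscaled on the right. Both classes ran together at low signal, and between 4096 and 8192 units the miRNA median was -1.44 against -0.76 for tsRNAs, or -0.92 against -0.24 unscaled.

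**Figure D3:**
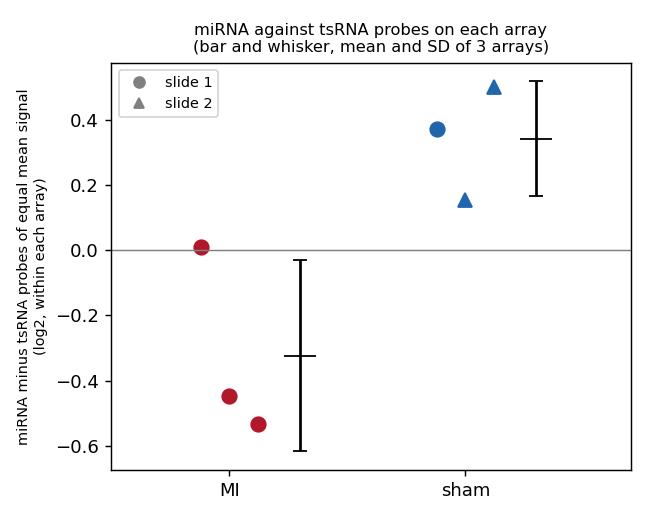
Mean log2 signal of miRNA probes minus that of tsRNA probes of equal mean signal on each array, for signals from 1024 to 16384 units, with the mean and SD of 3 arrays per group and the slide of each array. The MI arrays lay between -0.53 and 0.01 and the sham arrays between 0.15 and 0.50.

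Over all 11974 small RNAs tested, 491 differed between the groups, 37 higher and 454 lower in MI (92.5% lower). Scaling to the high-signal RNAs gave 88 higher and 26 lower (22.8% lower), no scaling gave 33 higher and 0 lower, quantile normalization gave 65 higher and 91 lower (58.3% lower), and high-signal RNAs alone, scaled to themselves, were 70.2% lower. With slide as a block or within slide 1 limma called 0 (1454 and 2598 with an unadjusted p under 0.05). The number was 0 without MI 2 (2159 unadjusted), 0 without sham 1 (1457 unadjusted), 115 without MI 3 and 1460 without sham 3. Without sham 2 it was 233, of which 91 were higher and 142 lower (60.9% lower). The groups were apart without overlap in all 491 RNAs, and in 24.3% of all those tested, where the average over the possible splits of the arrays is 10%. RNAs vary together on an array, so a higher share in 1 split does not by itself exceed chance. In the remaining class, PST, 6 of 581 tested RNAs were called higher and 42 lower. Adjusted over the list alone, 6 were higher and 73 lower. Its 2 largest rises were 1.68 and 1.31 and its 2 largest falls -1.45 and -1.43, and of the 42 falls 0 remained called without scaling or with scaling to the high-signal RNAs. Of the 6 rises 5 remained called in each of these settings. Of the 48 calls, 2 were not well above background on any array of one group and have only a bound there.

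As whole classes, PST RNAs were low relative to the other RNAs (camera adjusted p = 1.9e-08, median log2 difference -0.42), tsRNAs were low (adjusted p = 0.0197, median -0.16) and miRNAs high (adjusted p = 0.000331, although their median was -0.04). Each class was set against the rest, and miRNAs were most of the RNAs (9620), so these are not 3 separate findings. None of the 3 held with an estimated correlation (adjusted p = 0.647 for each). In fry, which asks whether the members of a class move one way, each adjusted p was 0.167. Among RNAs with a mean signal of at least 200, camera called 0 of the 3 classes (adjusted p = 0.804 for each). Without sham 2 camera also called 0 classes, with an adjusted p of 0.438 for PST, 0.514 for tsRNAs and 0.758 for miRNAs. The direction of 2 classes turned among the settings of camera, in no case past the threshold: tsRNAs were high with normexp (adjusted p = 0.777), with quantile normalization (adjusted p = 0.247, median 0.04), among RNAs with a mean signal of at least 200 and without sham 2, and miRNAs were low in the last 2 of these. PST RNAs were low in every setting.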

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

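Tests chosen only after the data were seen are those without scaling, with scaling to or a filter on high-signal RNAs, of the undetrended intensity, of slide 1 alone and of probes of equal signal. Counts below give all small RNAs, then tsRNAs, then miRNAs, against 491, 124 and 319. Quantile normalization gave 156, 64 and 67, the median in place of the 75th percentile 125, 49 and 61, no filter 279, 71 and 167, array weights 1503, 487 and 884, no scaling 33, 22 and 6, and scaling to the high-signal RNAs 114, 58 and 47. The slide block and slide 1 alone gave 0, 0 and 0 in limma, with 1454 and 2598 RNAs at an unadjusted p under 0.05. Normexp gave 211 tsRNAs, and high-signal RNAs scaled to themselves gave 200 miRNAs. An unadjusted p with a fold of at least 1.5 gave 1548 RNAs and 548 tsRNAs. Leaving out 1 array gave 0 to 1460 RNAs, 0 to 548 tsRNAs and 0 to 780 miRNAs: 0 without MI 2 (2159 RNAs at an unadjusted p under 0.05), 0 without sham 1 (1457), 115 without MI 3, 233 without sham 2 and 1460 without sham 3. Apart from the replicate block, the remaining settings left these counts within 1.5 times. The groups did not overlap in any called RNA, so signs could turn only with another scale or background correction. There the 26 higher tsRNAs kept theirs, and the 98 lower tsRNAs and 314 lower miRNAs did in all but scales set by 1 class at 1 level of signal, chosen after the data were seen: some of them turned on 4 and 5 of the 25, which left 0 to 98 and 0 to 314 of the falls called. The scale on which the largest number turned was set by 51 miRNAs, of which 40 were called lower themselves, so it cannot test the falls. The change of miRNA against tsRNA probes of equal signal stayed between -0.83 and -0.56 in 10 alternatives. The number of classes called by camera, 3, was 2 with no filter and with the other variance model, where the call of tsRNAs ended (adjusted p = 0.103 and 0.137), 1 with normexp, quantile normalization, the slide block, array weights and slide 1 alone, and 0 with either filter at a mean signal of 200, with an estimated correlation and without sham 2 (0 to 3 over single arrays left out), and directions turned for tsRNAs with normexp and quantile normalization, and for tsRNAs and miRNAs with either filter and without sham 2. The cause of these changes was not tested. The difference in detected RNAs, 12 tsRNAs and 61 PST RNAs more in MI, was 0.333 and 197.3 with the flag for a positive and significant signal, and that of 73.3 miRNAs was 1.67. Over single arrays left out these differences ranged from 9 to 16.5, from 30.3 to 102 and from 17.7 to 118. Replicate number as a block gave 1120, 421 and 591 calls and left the 3 classes called. The numbers share nothing in the labels: deviations of arrays with one number correlated at 0.118, -0.221 and 0.159, and 3 of 6 arrays correlated best with their own number, so this fit is not read as a paired analysis. The alternatives for types of tsRNA, amino acids, miRNA lists, tRNAs and precursors were not run, since the files do not pair identifiers with names. Whether probes of low signal report the RNA they are named for was not tested.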

Other observations

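The arrays also carried 50 mRNA probes with 10 spots each, which the comparisons of small RNAs did not use. Their signals were weak, at most 37.5 intensity units in a group mean, and 22 were well above background on at least 3 arrays. With the scaling of the 75th percentile, limma over the 50 probes called 5 lower in MI and 0 higher, and these 5 were named after their values were seen. This fit gave all 50 probes 1 common variance (SE 0.33). Their p-values therefore follow from the size of the difference and do not reflect the spread of the single probe. Slide was not a block in this fit. H2-Q7, a major histocompatibility complex class I gene, was at 14.5 ± 1.82 in MI and 22.7 ± 7.67 in sham (SD, n = 3 each), a log2 difference of -1.13 (limma adjusted p = 0.00965). Tm9sf1, which encodes a membrane protein, was at 9.04 ± 0.240 and 12.8 ± 2.70, a log2 difference of -1.01 (adjusted p = 0.0256). Gabrg1, a subunit of the GABA-A receptor, was well above background on all 3 sham arrays, at 4.97 ± 1.48, and on 0 MI arrays. Its MI value of 2.16 ± 0.563 and its log2 difference of -1.67 (limma adjusted p = 2.46e-05) are therefore only bounds. Gsta4 was well above background on 2 of 6 arrays and Bambi on 1, so their levels were not read. Without scaling the call of Bambi alone was left, and with quantile normalization that of Gabrg1 alone, so those of H2-Q7 and Tm9sf1 ended in both. With scaling to the high-signal RNAs the same 5 were lower. The median over the 50 probes was -0.49 with the 75th percentile, 0.04 without scaling and -0.10 with scaling to the high-signal RNAs.

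The tests weighed in the paragraphs on higher tsRNAs, on miRNA against tsRNA probes and on the surplus of falls were chosen after the results were seen, while the splits of the arrays were planned. The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 491 small RNAs, 124 tsRNAs and 319 miRNAs in limma, and the highest of the other splits gave 0 of each, so 1 of 10 splits gave as many in each case. At an unadjusted p under 0.05 the real split gave 2289 small RNAs and the highest other 1325. For the number of classes in camera, 9 of 10 splits gave 3, the real one among them, so a count of 3 classes arose for most groupings of these arrays.

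The 26 higher tsRNAs were also read on 25 other scales, each set by 1 class at 1 level of signal. On each of these scales 100% of the 26 had each MI value above each sham value, and 11 to 26 were called. On the scale least favourable to rises, tsRNAs of 64 to 128 units, their median difference was 1.42. The 26 were picked on a scale close to that one (median 1.48), so their separation there was nearly settled by the choice. None of the 25 scales removed the rises, but whether scaling is their cause cannot be decided from this list. Of the 26, 13 were called in each of 8 scalings and background corrections, as were 2 PST rises and 0 falls. Some of these settings raised every difference, so this count does not decide on scaling either. A difference between slides stays open. Among 28 tsRNAs picked without sham 1 as higher in MI (unadjusted p under 0.05 and a log2 difference above 1), sham 1, which shares the slide of the MI arrays, lay at a median of 0.0774 on a scale with the sham arrays of slide 2 at 0 and MI at 1, but it is the only array that parts slide from group. With slide as a block the median difference of the 26 was 1.63 with a median SE of 0.36, against 1.48 and 0.24 without it, and the calls ended as the SE grew and residual degrees of freedom fell from 4 to 3. The median difference did not shrink, while the smallest fell from 0.95 to 0.75 and the largest from 2.77 to 2.44. The 26 were called with sham 1 among the sham arrays, so neither these differences nor the lost calls decide on slide. A higher content of these tsRNAs in the infarct stays open as well, since 1 array cannot part these explanations.

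Between 1024 and 16384 units, a range chosen after the data were seen, miRNA probes were lower in MI relative to tsRNA probes of equal signal. From 256 to 1024 units the medians ran slightly the other way (-0.25 for miRNAs and -0.31 for tsRNAs). The change was seen at each separate level of signal in this range and was -0.33 at the smallest, between 1024 and 2048 units. It therefore did not rest on tsRNA probes above 16384 units, where the medians were closer (-0.86 for miRNAs and -0.70 for tsRNAs). No spot was flagged as saturated, but this flag reads the scan and cannot show whether a probe was filled in hybridisation. Probes of equal signal need not be filled alike, so saturation of tsRNA probes stays open. Slide stays open: sham 1 lay at -0.0663 on the scale from slide 2 sham (0) to MI (1), away from the MI arrays, but is again 1 array. A change in the cells of the infarcted tissue could also lower the miRNAs typical of heart muscle, and this was not tested, since the files do not pair identifiers with miRNA names.

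The surplus of falls over rises may come from the scale. The 75th percentile of each array fell among probes of low signal, and it was higher in MI (68.6 to 97.4) than in sham 1 and sham 2 (49.6 and 42.9). Only MI 3 (97.4) was above sham 3 (83.0). With scaling to the high-signal RNAs 22.8% of the calls were lower, against 92.5%, but a single array moved the share too, to 60.9% without sham 2. The high-signal RNAs had a median of -0.62 with the 75th percentile. Scaling to them therefore raised every difference and favoured a smaller share of falls in advance. The drop cannot tell falls made by the scale from falls in the RNA. Whether the signal of the low-signal probes differs between the groups because of the RNA or of the labelling and hybridisation was not tested, and which scale is right stays open.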
